A study of Mus musculus with 12 samples.

How the data were processed

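The series measured RNA by sequencing in 12 liver libraries from C57BL/6 mice aged 12 weeks, per the labels. The labels give a genotype, p53 wild type (wt) or p53 knockout (ko), and a diet, normal or HFD (high-fat diet). The 12 libraries form 4 groups of 3, called wt_normal, ko_normal, wt_HFD and ko_HFD here. Groups and replicate numbers were taken from the labels of each library. The labels do not say that the replicates of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. The length of the diet, the time of day at sampling and the feeding state are not given in the sources used here.

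The deposited files hold 1 column of whole-number read counts per gene for each library. Per the submitters' processing notes, the authors used CASAVA 1.8 and Bowtie 0.12.2, and the notes name the genome builds mm8 and mm9 without saying what each was used for. The counting tool, the gene annotation and the use of strand are not given in the sources used here. The counts were used as deposited. The files list 52636 Ensembl gene identifiers, of which 52403 were matched to a symbol. Gene positions are those of GENCODE release M21 on build GRCm38, looked up by gene identifier. They are not the authors' coordinates.

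Total counts per library ran from 15465187 to 20492567. The pairs of replicates within a group were compared by a chi-square test of their counts over genes with at least 20 counts, and the statistic per degree of freedom ran from 39.5 to 199. Counting error alone gives a value near 1, so these values argue against replicates that only repeat the sequencing of 1 library. They do not show whether the libraries came from separate animals. Genes with low counts were removed with edgeR's filterByExpr, which left 14433 genes. Normalised read counts are given as CPM, the scaled counts that edgeR computes from library totals and TMM factors. Differences were tested with edgeR 4.0.16 by the quasi-likelihood F-test, in 1 fit of the 4 groups to all 12 libraries, with 8 residual degrees of freedom and 4.66 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14433 genes of a comparison. There were 6 comparisons: ko against wt on each diet, HFD against normal diet in each genotype, the difference between the ko effects on HFD and on normal diet, and ko against wt averaged over both diets. Fold changes are the fitted log2 values with their standard error (SE), and group levels are mean CPM ± SD of 3 libraries. All adjusted p-values of single genes come from this two-sided test unless another is named.

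Before the data were examined, 34 lists of genes (pathways, processes and markers of cell types) with 488 entries were fixed. Each list with at least 3 tested members was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the correlation between genes preset at 0.01. The p-values were adjusted over the 33 lists tested. The estimated correlation of camera and the rotation test fry served as checks. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The genes named below were chosen by a rule that was also fixed before the data were examined. It takes Trp53 and Sqle in each comparison, then up to 8 called genes with the largest rise and up to 8 with the largest fall among those whose groups do not overlap, leaving out predicted gene models. It adds up to 4 called members of each list with the smallest adjusted p, and the 4 members with the smallest p of the cholesterol synthesis and p53 target lists. Where fewer than 5 genes were called, it adds the 5 genes with the smallest p. At most 2 members of a gene family are named. Genes named outside this rule are said to have been chosen after their values were seen.

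A gene with no count in a group was set against a floor of 3 counts summed over the group, which gives a lower bound of its fold. With 1 to 3 counts, the ratio of summed CPM is given with its exact 95% interval. Floors and intervals cover counting error only. Reads of genes with near-identical copies, of overlapping genes and of antisense neighbours cannot be told apart in these counts. This concerns the mitochondrial tRNA genes, Srp54a, Cyp3a11, Cyp3a59, Cyp2a5, Gsta2 and Gstm1 in particular, whose values are uncertain for that reason.

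The edgeR test was tried on simulated counts drawn from the means and totals of these libraries with 200 changed genes. For ko against wt on normal diet it recovered 19.4% of the 2-fold and 78.6% of the 4-fold changes, over 14141 genes. For ko against wt averaged over both diets it recovered 46.4% and 89.8% over 14166 genes, and for the difference between the ko effects 4% and 43.4% over 14165 genes. Alternatives were other fits (only the groups compared, replicate number as a block, each library left out in turn), other filters, other scalings, the Wald test of DESeq2 1.42.0, voom with sample weights and a minimum of a 2-fold change. A fit with a circadian clock index as covariate and an exact permutation of list means were added after the data had been seen. The index, the log2 ratio of the clock genes Arntl to Dbp, was lower in every ko library than in every wt library. For ko against wt, a call that ends in that fit therefore cannot tell clock phase from genotype. Calculations used R 4.3.3, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.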

Results

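Liver transcripts were counted in 3 wt and 3 ko libraries on a normal diet and in 3 wt and 3 ko libraries on HFD. Total counts were 15465187 to 18584789 in wt_normal, 17186008 to 20492567 in ko_normal, 16751342 to 17980836 in wt_HFD and 15757330 to 18615222 in ko_HFD. The title of the series names the squalene epoxidase gene Sqle as regulated by p53, and the design sets wt against ko livers on each diet.

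Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), the gene encoding p53, was measured in every library. Its normalised read count was 14.5, 15.6 and 16.3 CPM in the wt_normal libraries and 8.54, 10.7 and 24.5 CPM in the wt_HFD libraries. It was 0.273, 0.399 and 1.62 CPM in the ko_normal libraries and 0.701, 0.748 and 0.752 CPM in the ko_HFD libraries. Each ko library thus lay below each wt library, with 5 to 28 counts against 142 to 432.

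**Figure D1:**
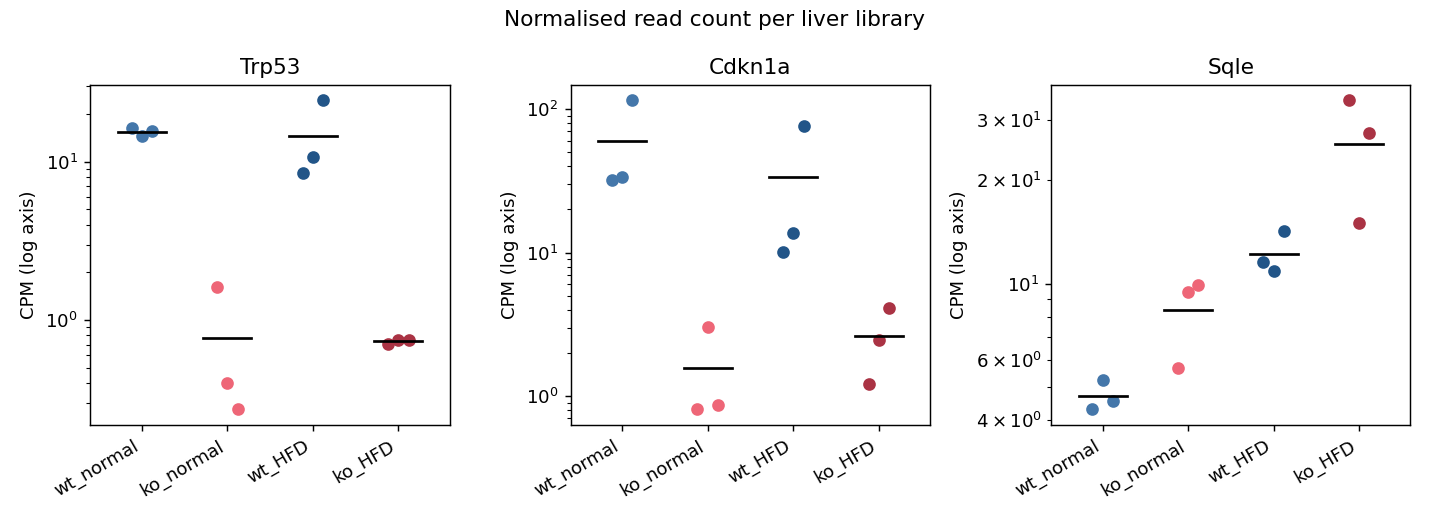
Normalised read count in CPM (log axis) of Trp53, Cdkn1a and Sqle in the 12 liver libraries, by group. Points are libraries and lines are group means of 3. Trp53 and Cdkn1a lay lower in each ko library than in each wt library, and mean Sqle was 4.70 CPM in wt_normal and 25.6 CPM in ko_HFD.

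Library wt_normal replicate 2 stood apart, as shown by genes that were chosen after their values were seen. Skeletal muscle marker genes took 0.987% of its counts and at most 0.00118% in any other library. Acta1, skeletal muscle actin, had 59134 counts there against at most 48 elsewhere, and Ckm, muscle creatine kinase, had 14292 against at most 13. Transcripts of B cells were also highest there. Ighm, the heavy chain of immunoglobulin M, had 107 CPM against at most 7.46 CPM in the other libraries, and Cd79a, a subunit of the B cell receptor, had 12.8 CPM against at most 1.81 CPM. The mitochondrially encoded genes took 14.2% of the counts in ko_normal replicate 1 and 9.98% in ko_HFD replicate 2, against 4.01% to 7.03% in the other 10 libraries.

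**Figure D2:**
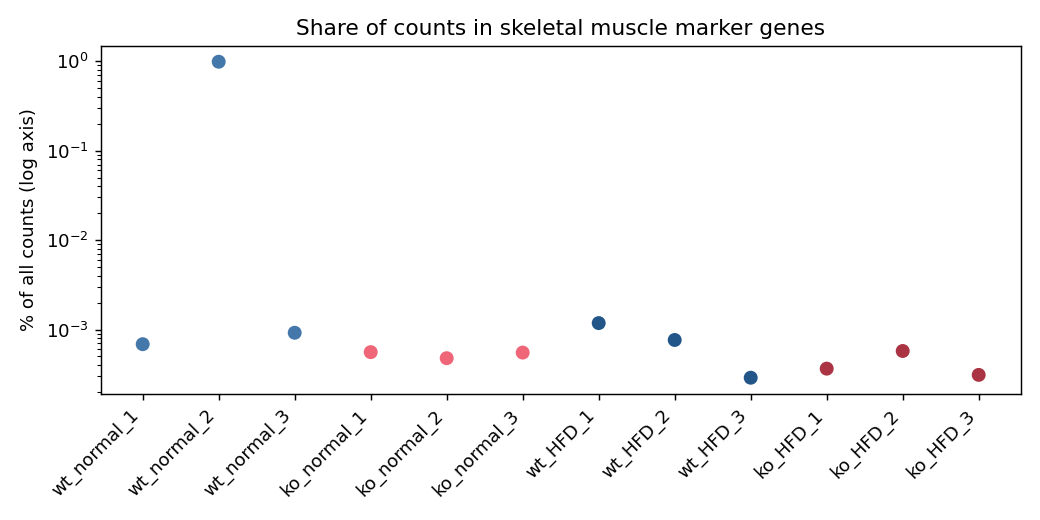
Share of all counts in the skeletal muscle marker genes, in percent (log axis), for each library, coloured by group. Library wt_normal replicate 2 is at 0.987% and the others are at 0.00118% or less.

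The comparison of ko with wt on the normal diet asks what loss of p53 changes in the liver without the dietary load. Slc2a2, the glucose transporter GLUT2, rose from 39.4 ± 12 to 148 ± 20 CPM (SD, n = 3) in ko livers, a log2 change of 1.91 (SE 0.24). Serpina12, which encodes the adipokine vaspin, rose 5.97-fold, and Srebf1, a transcription factor of lipid synthesis, rose 3.51-fold. Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose 2.04-fold. Cdkn1a, the cell cycle inhibitor p21 and a p53 target, fell from 60.0 ± 47 to 1.58 ± 1.3 CPM, and Trp53 fell by 4.35 on the log2 scale (SE 0.55).

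In edgeR's test 30 genes were called, 21 higher and 9 lower in ko, with adjusted p = 0.00984 for Trp53, 0.00984 for Slc2a2, 0.00234 for Serpina12 and 0.0471 for Cdkn1a. The other named rises were Rgs16, a regulator of G protein signalling (25.3-fold), the centromere protein gene Cenpm (8.03-fold), the forkhead factor gene Foxq1 (5.38-fold), Klhdc7a (5.27-fold) and the methyltransferase gene Vcpkmt (4.29-fold). The mitochondrial tRNA genes mt-Tg and mt-Tr also rose. Mt-Tg had no count in wt_normal and was at least 43.6-fold higher in ko_normal, and mt-Tr was higher by a ratio of 29.6 (95% interval 9.81 to 146). The other named falls were Cpe, carboxypeptidase E (log2 change -5.03), the actin-severing protein gelsolin, Gsn (-2.85), the protease inhibitor gene Serpine2 (-1.25) and Htatip2 (-1.01). Srp54a, a signal recognition particle gene with near-identical copies, was lower by a ratio of 35.2 (9.41 to 297).

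Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), the enzyme that oxidises squalene in cholesterol synthesis, was measured at 4.70 ± 0.48 CPM in wt_normal and 8.36 ± 2.3 CPM in ko_normal. Its log2 change was 0.83 (SE 0.30, adjusted p = 0.209 by edgeR), higher in 3 of 3 ko libraries than in every wt library. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. Among the 20 cholesterol synthesis genes none was called over all genes by edgeR, and 7 were higher when adjusted over the list alone. The members with the smallest p were Msmo1 (0.98, SE 0.19), Dhcr7 (0.54), Nsdhl (1.01) and Mvk (0.76), enzymes of sterol synthesis. The median log2 change of the list was 0.47, which camera called at adjusted p = 0.000625, and it had adjusted p = 0.216 with an estimated correlation.

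Camera called 13 of 33 lists on the normal diet, 5 of them also called by fry, 7 with the clock index as covariate and none with an estimated correlation, where the smallest adjusted p was 0.108, for sterol sensing and uptake. That list had a median of 0.48 (adjusted p = 0.000613 with the preset correlation) and 2 called members. Interferon response genes had a median of 1.02 (adjusted p = 1.82e-06, 0.324 with an estimated correlation) with no member called and 7 higher when adjusted over the list alone, and its median was 0.68 without ko_normal replicate 3. The 25 p53 target genes had a median of -0.30 (adjusted p = 0.0207, 0.216 with an estimated correlation). Of these, 1 fell and 5 were lower when adjusted over the list alone. The members with the smallest p after Cdkn1a were Aen, a p53-induced nuclease (-1.32), Ddit4, an inhibitor of mTOR signalling (-1.89), and Phlda3 (-3.17), with adjusted p of 0.074, 0.13 and 0.141 over all genes. The list's call ended without ko_normal replicate 2 (median -0.30, adjusted p = 0.0559). The 13 mitochondrially encoded genes had a median of 1.08 (adjusted p = 0.000222, 0.505 with an estimated correlation), in a comparison where ko_normal replicate 1 held 14.2% of its counts in them, and the call ended without that library (median 0.26, adjusted p = 0.105). The median turned to -0.18 with the clock index as covariate (adjusted p = 0.944).

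Of the cell type lists, those of endothelial and stellate cells were called lower in ko_normal, while macrophage markers were not (median -0.16, adjusted p = 0.254). All 11 endothelial markers had a negative log2 change, with a median of -0.96 (camera adjusted p = 2.77e-06, 0.216 with an estimated correlation). All 13 markers of stellate cells and fibrosis were negative too, with a median of -1.49 (adjusted p = 5.76e-06, 0.216 with an estimated correlation). Without the library with muscle transcripts these medians were -0.75 and -1.23. The skeletal muscle list had a median of -9.99 (adjusted p = 0.00771, 0.561 with an estimated correlation) and -0.88 without that library, where its call ended (adjusted p = 0.112). Camera also called bile acid synthesis and transport (median 0.24, adjusted p = 0.0264, 0.216 with an estimated correlation) and fatty acid and triglyceride synthesis (0.29, adjusted p = 0.0264, 0.216 with an estimated correlation). The remaining calls were the endoplasmic reticulum (ER) stress response (0.60, adjusted p = 0.000874, 0.288 with an estimated correlation), male-biased genes (0.23, adjusted p = 0.0313, 0.525 with an estimated correlation) and circadian clock genes (0.64, adjusted p = 0.0457, 0.216 with an estimated correlation). Calls ended for bile acid synthesis without wt_normal replicate 2 (adjusted p = 0.141), for fatty acid synthesis without wt_normal replicate 1 (0.104) or ko_normal replicate 2 (0.269, median 0.07), and for male-biased genes without wt_normal replicate 2 (0.2) or ko_normal replicate 1 (0.116). The clock call ended without wt_normal replicate 1, ko_normal replicates 1 or 2, wt_HFD replicate 2 or any of ko_HFD replicates 1, 2 and 3, with adjusted p from 0.0588 to 0.135, and with DESeq2 size factors (0.0536). With the clock index as covariate, chosen after the data were seen, the calls of fatty acid synthesis, p53 targets, clock, male-biased, endothelial and mitochondrially encoded genes ended.

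The count of 30 genes depended on single libraries. It was 3 without ko_normal replicate 3, 6 without wt_normal replicate 2, 7 without wt_normal replicate 3, 8 without ko_normal replicate 2, 16 without ko_normal replicate 1 and 84 without wt_normal replicate 1. Because the spread is shared by the 4 groups, it was also 77 without wt_HFD replicate 2, 15 without ko_HFD replicate 1 and 12 without ko_HFD replicate 2. Of the 18 called genes named here, 17 lost their call without ko_normal replicate 3 and 15 without wt_normal replicate 2. Trp53 lost it without ko_normal replicate 2 (-4.02, adjusted p = 0.0566) or replicate 3 (-3.94, adjusted p = 0.066), and Serpina12 kept its call when any of the 12 libraries was left out.

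The same comparison on HFD asks what loss of p53 changes under dietary load. Ddah1, which degrades an inhibitor of nitric oxide synthesis, was higher in ko_HFD than in wt_HFD livers, at 57.2 ± 9.6 against 18.5 ± 1.1 CPM (SD, n = 3), a log2 change of 1.63 (SE 0.18). Akr1d1, a reductase of bile acid synthesis, rose 4.21-fold, from 16.7 ± 3.7 to 70.3 ± 3.6 CPM. Hoga1, a mitochondrial enzyme of hydroxyproline breakdown, rose 2.18-fold. Serpine2 fell by 1.37 on the log2 scale (SE 0.21) and Trp53 by 4.30 (SE 0.56). Mt-Tg had no count in wt_HFD and was at least 54.9-fold higher in ko_HFD.

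In edgeR's test 10 genes were called on HFD, 6 higher and 4 lower in ko, with adjusted p = 0.00807 for Ddah1, 0.0136 for Akr1d1, 0.0136 for Trp53 and 0.0385 for Serpine2. Sqle was measured at 12.2 ± 1.8 CPM in wt_HFD and 25.6 ± 9.7 CPM in ko_HFD, a log2 change of 1.06 (SE 0.29, adjusted p = 0.343 by edgeR), with every ko_HFD library above every wt_HFD library. The exact permutation p was 0.1, the smallest possible. No cholesterol synthesis gene was called by edgeR over all genes, and 6 were higher when adjusted over the list alone, among them Sc5d (0.78), Hmgcs1 (0.96) and Nsdhl (1.09). The list's median was 0.37 (camera adjusted p = 0.000211, 0.24 with an estimated correlation, 0.0663 by fry) and 0.15 without ko_HFD replicate 1. The p53 targets with the smallest p were Cdkn1a (-3.68, SE 0.86, adjusted p = 0.267), Btg2 (-3.12), Aen (-0.87) and Trp53inp1 (-1.47), none of which passed. The p53 target list had a median of -0.38 (camera adjusted p = 0.00609, 0.133 with an estimated correlation), and its call ended without wt_HFD replicate 3 (adjusted p = 0.0625).

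Camera called 11 lists on HFD, 4 of them also called by fry, 7 with the clock index as covariate and none with an estimated correlation, and it called 7 lists without wt_HFD replicate 3. Xenobiotic metabolism genes had a median of 0.59 (adjusted p = 7.1e-06, 0.133 with an estimated correlation), with 4 of 17 members higher when adjusted over the list alone, and a median of 0.94 without wt_HFD replicate 3. Acute phase genes had a median of -0.60 (adjusted p = 8.11e-08, 0.449 with an estimated correlation), which was -1.53 without ko_HFD replicate 1 and -0.34 without ko_HFD replicate 2. This group varied within ko_HFD, where Saa1, serum amyloid A, chosen after its values were seen, had 15302 CPM in replicate 1, 169 CPM in replicate 2 and 271 CPM in replicate 3. ER stress genes had a median of -0.40 (adjusted p = 0.000171, 0.282 with an estimated correlation) and interferon response genes 0.70 (adjusted p = 7.1e-06, 0.449 with an estimated correlation). T and NK cell markers, whose wt_HFD means were 1.33 CPM or less, had a median of 0.89 (adjusted p = 7.1e-05, 0.137 with an estimated correlation). Fatty acid and triglyceride synthesis had 0.52 (adjusted p = 0.00165, 0.133 with an estimated correlation). Immediate early genes (-1.20, adjusted p = 0.0259, 0.524 with an estimated correlation), mitochondrially encoded genes (0.47, adjusted p = 0.00481, 0.513 with an estimated correlation) and endothelial markers (-0.40, adjusted p = 0.00481, 0.471 with an estimated correlation) lost their calls without wt_HFD replicate 3, with medians of -0.06, 0.35 and -0.21. Immediate early genes also lost theirs without ko_HFD replicate 1 (adjusted p = 0.0741) or 2 (0.0646), mitochondrially encoded genes without wt_HFD replicate 1 (0.055) or ko_HFD replicate 2 (0.299, median 0.10) and endothelial markers without ko_HFD replicate 1 (0.254, median -0.20). With the clock index as covariate these 3 calls and that of ER stress genes ended. Without wt_HFD replicate 2 the mitochondrial and endothelial medians were 0.76 and -0.25. The ER stress median was -0.21 without wt_HFD replicate 3, the interferon median 0.36 without ko_HFD replicate 3 and the fatty acid synthesis median 0.25 without ko_HFD replicate 1.

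The count on HFD was 2 without any single one of the ko_HFD replicates 1, 2 and 3, 5 without wt_HFD replicate 3 and 6 without ko_normal replicate 3. Trp53 lost its call without ko_HFD replicate 1, 2 or 3 (-4.27, -4.32 and -4.32, adjusted p = 0.0697, 0.0963 and 0.0966). Ddah1 kept its call in each of the 21 alternatives, with a log2 change of 1.55 to 1.76. Between the diets, which share no libraries, 7 genes were called for ko against wt in the same direction, against 0.0112 for independent lists. Trp53 itself and mt-Tg are among the 7. Both comparisons come from 1 fit with a spread shared over the 4 groups, so their calls are not fully independent. The log2 changes of all 14433 genes correlated across genes with r = 0.394, against 0.003 in simulated data without effects. Genes are not independent replicates, so no p is given for that correlation.

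The comparison of HFD with normal diet in wt livers asks what the diet changes while p53 is present. Cyp3a11, the main liver cytochrome of the Cyp3a family, fell from 1475 ± 190 to 114 ± 43 CPM (SD, n = 3), a log2 change of -3.69 on HFD (SE 0.31). Gsta2, a glutathione transferase, fell from 18.8 ± 1.6 to 0.841 ± 0.51 CPM. Msmo1, a sterol demethylase, rose from 12.1 ± 2.5 to 43.7 ± 5.9 CPM, and Serpina12 rose 12.4-fold. Gadd45a, a DNA damage response gene, rose 14.0-fold, and Gdf15, a stress-induced hormone on the p53 target list, rose 13.2-fold.

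In edgeR's test 100 genes were called, 62 higher and 38 lower on HFD, with adjusted p = 0.000221 for Cyp3a11, 0.00151 for Gsta2, 0.0014 for Msmo1 and 0.000127 for Serpina12. The other named rises were Fabp5, a fatty acid binding protein (7.73-fold), Foxq1 (6.00-fold), Serpina4-ps1 (10.7-fold), Adgrv1 (8.33-fold), Nat8f5 (6.95-fold) and the serum amyloid gene Saa4 (4.80-fold). The other named falls were Cyp3a59 (-4.02), Etnppl (-2.87), Acmsd of tryptophan breakdown (-2.76), the organic anion transporter Slco1a4 (-2.51), Snhg11 (-2.42) and Prickle1 (-1.88). Ass1 of the urea cycle (-1.58), Akr1d1 (-1.42), Gstm1 (-1.35) and the quinone reductase gene Nqo1 (-1.28) also fell. Sqle was measured at a log2 change of 1.38 (SE 0.30, adjusted p = 0.0569 by edgeR) and did not pass. Trp53 had a log2 change of -0.09 (SE 0.45).

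Of 20 cholesterol synthesis genes, 3 rose on HFD in wt livers, and 10 were higher and 1 lower when adjusted over the list alone. Those that rose were Msmo1 (1.85, SE 0.19), Cyp51 (1.35, SE 0.20) and Mvd (1.39, SE 0.24). The list's median was 0.60 (camera adjusted p = 4.49e-07, 0.167 with an estimated correlation) and 0.33 without wt_HFD replicate 3. Of the sterol sensing and uptake list, whose median of 0.06 was not called (adjusted p = 0.137), Stard4, a sterol transfer protein, rose 2.38-fold and Insig1 rose by a log2 change of 0.84 (SE 0.17, adjusted p = 0.0499). Soat2, which esterifies cholesterol, rose 2.70-fold.

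All 17 ER stress genes had a positive log2 change on HFD in wt livers, with a median of 0.96 (camera adjusted p = 3.93e-11, 0.167 with an estimated correlation). Of these, 2 rose, Creld2 (3.02-fold) and Manf (2.33-fold), and 12 were higher when adjusted over the list alone. Acute phase genes had a median of 1.42 (adjusted p = 9.74e-08, 0.702 with an estimated correlation) with 1 called member. Xenobiotic metabolism had a median of -0.41 (adjusted p = 0.00623, 0.633 with an estimated correlation), with 3 of 17 members called lower, and the call ended without wt_HFD replicate 3 (adjusted p = 0.0749). That median was -0.22 without wt_normal replicate 1, -0.18 without wt_HFD replicate 1 and -0.86 without wt_HFD replicate 2. Interferon response genes had a median of 0.64 (adjusted p = 0.00144, 0.702 with an estimated correlation) and immediate early genes 1.91 (adjusted p = 0.037, 0.702 with an estimated correlation). Both lost their calls without wt_HFD replicate 3, with medians of 0.31 and -0.03. Immediate early genes also lost theirs without wt_normal replicate 1 (adjusted p = 0.123), ko_normal replicate 2 (0.0537) or ko_HFD replicate 1 (0.0573). Endothelial markers had a median of -0.66 (adjusted p = 0.00702, 0.702 with an estimated correlation), and their call ended without wt_HFD replicate 1 (adjusted p = 0.0807) and with the clock index as covariate (0.243).

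The lists of stellate cell (median -0.89, adjusted p = 0.00681), B cell (-2.99, 0.0129), erythroid (-1.18, 0.0284) and skeletal muscle markers (-8.85, 0.0293) were called lower by camera, each with adjusted p = 0.702 with an estimated correlation. These 4 calls ended without wt_normal replicate 2, the library with muscle transcripts, where the medians were -0.45, -1.03, -0.74 and 0.06. Camera called 11 lists for HFD in wt livers, 3 of them also called by fry, and it called 7 lists without wt_normal replicate 2 and 5 without wt_HFD replicate 3. With total count scaling the B cell, erythroid and muscle calls ended (adjusted p = 0.0635, 0.0762 and 0.154). The stellate, erythroid and muscle calls also ended without wt_HFD replicate 3 (adjusted p = 0.0851, 0.206 and 0.249), and the muscle call without ko_normal replicate 1 (0.0518).

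The count of 100 genes was 9 without wt_normal replicate 3, 19 without wt_HFD replicate 2, 22 without wt_HFD replicate 1, 23 without wt_normal replicate 2, 24 without ko_normal replicate 3, 57 without ko_HFD replicate 2 and 58 without ko_normal replicate 2. Of the 31 called genes named for this comparison, 24 lost their call without wt_normal replicate 3, 21 without wt_HFD replicate 1 or 2, 17 without wt_normal replicate 2 and 18 with only the 2 groups compared, among them Gadd45a, Gdf15, Mvd, Stard4, Insig1, Soat2 and Manf in more than 1 of these. Serpina12, Gsta2, Cyp3a59, Cyp3a11 and Msmo1 kept their calls in all 21 alternatives. With libraries scaled by total count, which lowered the median log2 change of all genes to -0.21, 34 genes were higher and 64 lower, against 62 and 38. The comparisons of ko on the normal diet and of HFD in wt share the wt_normal libraries and had 7 genes called in both in the same direction, against 0.114 for independent lists. Their log2 changes correlated across genes with r = 0.522 (0.497 in simulated data without effects) and a covariance of 0.2 (0.0888 simulated), and part of any excess may come from the shared libraries. The comparisons of ko on HFD and of HFD in wt share the wt_HFD libraries and had 2 genes called in both, in opposite directions, with r = -0.313 (-0.503 simulated) and a covariance of -0.0964 (-0.0906 simulated).

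The comparison of HFD with normal diet in ko livers asks what the diet changes without p53. It left no gene past the threshold in edgeR's test. On simulated counts that test recovered 16.3% of 2-fold and 77.8% of 4-fold changes for this comparison, so most 2-fold changes would be missed. The genes with the smallest p were Msmo1, from 23.8 ± 2.7 to 60.2 ± 9.4 CPM (log2 change 1.34, SE 0.19), Cyp51, a sterol demethylase (1.30, SE 0.20), Cyp2c69 (-4.14, SE 0.62), Tiam2 (-1.45, SE 0.22) and Cyp3a11 (-1.85, SE 0.29), each with adjusted p = 0.0713 (SD, n = 3, edgeR). Sqle was measured at a log2 change of 1.61 (SE 0.29, adjusted p = 0.209 by edgeR). At an unadjusted p under 0.05 there were 812 genes, somewhat over the share of 0.05 of the 14433 genes that chance alone gives. The adjusted count was 37 by DESeq2 and 6 by voom with sample weights.

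Cholesterol synthesis genes had a median log2 change of 0.53 in ko livers on HFD (camera adjusted p = 5.69e-12, 0.0665 with an estimated correlation), with 9 of 20 members higher when adjusted over the list alone, Mvd among them (1.25). Interferon response genes (median 0.42, adjusted p = 0.00924, 0.968 with an estimated correlation) and T and NK cell markers (0.73, adjusted p = 0.00924, 0.585 with an estimated correlation) were also called by camera. Both of these calls ended without ko_HFD replicate 3 (medians 0.17 and 0.67). The interferon call also ended without ko_normal replicate 1 (median 0.14), and the T and NK call without ko_normal replicate 3 (median 0.49). The interferon median was 0.69 without ko_normal replicate 3 and 0.66 without ko_HFD replicate 1, and the T and NK median 0.44 without ko_normal replicate 2. The p53 targets with the smallest p were Gdf15 (2.07), Bbc3 (-0.88), Plk2 (-0.68) and Sesn1 (-0.65), and the p53 list had a median of 0.02 (adjusted p = 0.93). Without ko_HFD replicate 2 the count of genes was 6, and without wt_HFD replicate 1 it was 1. The count of 3 lists was 6 without ko_normal replicate 2, 9 without ko_HFD replicate 1 and 6 without ko_HFD replicate 2. Of the 100 genes called for HFD in wt livers, 89 had the same sign in ko livers, which share no libraries with that comparison. The log2 changes of all genes correlated across genes with r = 0.354 (0.00141 in simulated data without effects), and genes are not independent replicates.

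The difference between the ko effects on HFD and on normal diet asks whether p53 loss acted differently on the diets. No gene passed edgeR's test. At an unadjusted p under 0.05 there were 725 genes, near the share of 0.05 of the 14433 genes that chance alone gives. The adjusted count was 19 by DESeq2 and 1 by voom with sample weights. The smallest p belonged to Serpina12 (log2 difference -2.74, SE 0.36, adjusted p = 0.0587), whose mean was 17.8 ± 6.9 CPM in wt_normal, 106 ± 15 in ko_normal, 220 ± 41 in wt_HFD and 197 ± 25 in ko_HFD (SD, n = 3, edgeR). Next were Foxq1 (-3.09), Cdk5rap3 (-1.16), Igha, the heavy chain of immunoglobulin A (3.48), and Derl3 of ER protein degradation (-2.41). Sqle had a difference of 0.23 (SE 0.41, adjusted p = 0.999 by edgeR) and Trp53 of 0.05 (SE 0.76). Cholesterol synthesis genes had a median of -0.03 (camera adjusted p = 0.81), with Hsd17b7 (0.83), Tm7sf2 (0.56), Msmo1 (-0.51) and Mvk (-0.53) at the smallest p. The p53 target list had a median of 0.07 (camera adjusted p = 0.815), with Phlda3 (3.25), Btg2 (-2.31), Ddit4 (1.44) and Gdf15 (-1.66) at the smallest p. The count was 1 without wt_normal replicate 1 and 1 without wt_normal replicate 3.

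The average of the ko effects over both diets asks what loss of p53 changes irrespective of diet, with 6 libraries a side. On average Trp53 fell by 4.33 on the log2 scale (SE 0.39) and Cdkn1a by 4.45 (SE 0.63), and Aen fell by 1.09. Sqle rose 1.93-fold (log2 change 0.95, SE 0.21), together with Nsdhl (1.05), Msmo1 (0.72), Sc5d (0.68) and Dhcr7 (0.54), 4 further enzymes of cholesterol synthesis. Slc2a2 rose 2.73-fold, and Fasn, fatty acid synthase, rose 1.85-fold. Irf7, a transcription factor of the interferon response, rose 2.17-fold, with means of 46.9 ± 2.8 in wt_normal, 120 ± 47 in ko_normal, 86.2 ± 8.1 in wt_HFD and 160 ± 9.5 CPM in ko_HFD (SD, n = 3).

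In edgeR's test 168 genes were called, 114 higher and 54 lower in ko, with adjusted p = 0.000411 for Trp53, 0.00666 for Cdkn1a, 0.0019 for Slc2a2 and 0.0474 for Sqle. For Sqle, 400 exact permutations of the genotype labels within the diets gave p = 0.005, the smallest possible. That p is not adjusted over genes. Sqle was tested because the title of the series names it, and the title may rest on these same data. Its call ended in 13 of 20 alternatives, whose log2 changes all stayed positive, from 0.83 to 1.24, with adjusted p from 0.00145 to 0.231. Among them it ended without any of wt_normal replicates 1, 2 and 3, ko_normal replicates 2 and 3, wt_HFD replicates 1, 2 and 3 and ko_HFD replicates 1 and 3 (log2 change 0.83 to 1.01). The self-test of this comparison, which found 46.4% of 2-fold changes, covers changes of about this size.

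**Figure D3:**
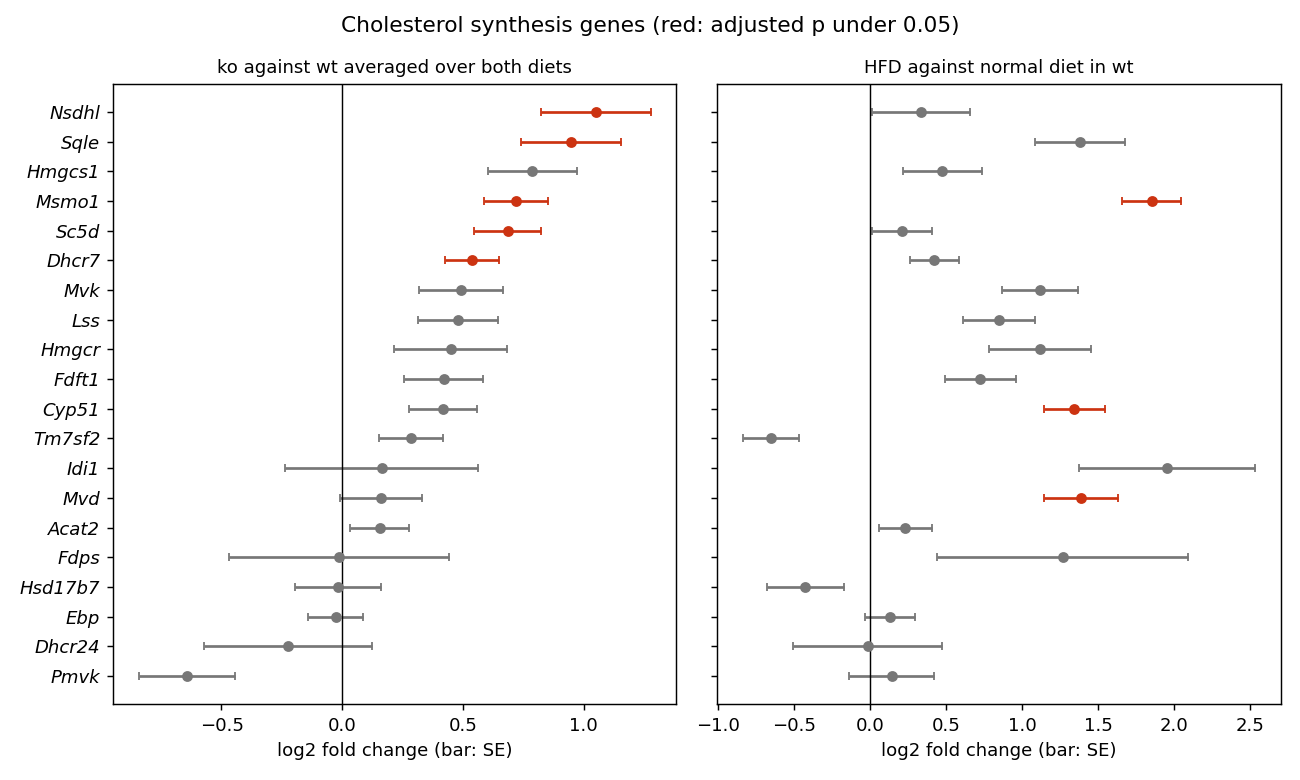
Log2 fold change with SE (bars) of the 20 cholesterol synthesis genes, for ko against wt averaged over both diets and for HFD against normal diet in wt. Red points passed an adjusted p of 0.05: 5 genes in the first panel, Sqle at 0.95 among them, and 3 in the second.

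Of 20 cholesterol synthesis genes 5 rose in ko livers averaged over both diets, and 10 were higher and 1, Pmvk (-0.64, chosen after its value was seen), lower when adjusted over the list alone. Of these 5 calls 0 were kept without wt_normal replicate 2, ko_normal replicate 3, wt_HFD replicate 2 or ko_HFD replicate 3, 1 without wt_normal replicate 1, wt_normal replicate 3, ko_normal replicate 2 or ko_HFD replicate 1, 2 without ko_normal replicate 1 or wt_HFD replicate 3 and 3 without wt_HFD replicate 1 or ko_HFD replicate 2. Camera called 12 lists, none of them with an estimated correlation and 9 of them also by fry, which lost acute phase, mitochondrially encoded and skeletal muscle genes. With the clock index as covariate, chosen after the data were seen, 7 of the 12 were called, without p53 targets, xenobiotic metabolism, acute phase, mitochondrially encoded and endothelial genes. The cholesterol list's median was 0.42 (camera adjusted p = 5.31e-05, 0.195 with an estimated correlation). Sterol sensing and uptake had a median of 0.52 (adjusted p = 0.00145, 0.0844 with an estimated correlation) and 5 called members, among them Srebf1 (1.30, SE 0.22), Insig1 (0.60), the lipoprotein receptor gene Scarb1 (0.52) and Stard4 (0.78). Fatty acid and triglyceride synthesis had a median of 0.42 (adjusted p = 0.00135, 0.0844 with an estimated correlation), with 6 members higher and 1 lower when adjusted over the list alone. Bile acid synthesis and transport had a median of 0.18 (adjusted p = 0.0274, 0.249 with an estimated correlation), with Akr1d1 called (1.40, SE 0.19), and its call ended without wt_normal replicate 2 (adjusted p = 0.0756), wt_HFD replicate 1 (0.0752, median 0.12) or ko_HFD replicate 3 (0.0605). Xenobiotic metabolism had a median of 0.45 (adjusted p = 0.00131, 0.249 with an estimated correlation), with Cyp2a5 called (3.46-fold).

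The p53 target list had a median of -0.30 averaged over both diets (camera adjusted p = 0.00271, 0.0844 with an estimated correlation), with 2 of 25 members called lower and 7 when adjusted over the list alone. Trp53inp1 (-1.53, SE 0.41, adjusted p = 0.0893 by edgeR) and Ccng1 (-0.99) did not pass over all genes, and Trp53inp1 turned to 0.26 with the clock index as covariate, where the list's call ended (adjusted p = 0.112). Interferon response genes were all positive, with a median of 0.73 (adjusted p = 8.47e-08, 0.273 with an estimated correlation), and 5 of 17 rose, among them Irf7, the guanylate binding protein gene Gbp3 (2.33-fold), Ifi44 (3.89-fold) and Ifit3 (2.32-fold). Ifi208 had 3 counts in the 6 wt libraries and was higher in ko by a ratio of 28.1 (95% interval 9.30 to 139). Acute phase genes had a median of -0.37 (adjusted p = 0.00131, 0.626 with an estimated correlation), with no member called by edgeR. That median was -0.23 without ko_normal replicate 1, -0.95 without ko_HFD replicate 1, -0.18 without ko_HFD replicate 2 and -0.22 without ko_HFD replicate 3.

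Endothelial markers had a median of -0.71 (camera adjusted p = 7.18e-06, 0.249 with an estimated correlation), with Lyve1, a receptor of sinusoidal endothelium, called lower (-1.82, SE 0.35). Stellate cell markers had a median of -0.96 (adjusted p = 0.000108, 0.249 with an estimated correlation) and of -0.45 without wt_HFD replicate 2, with Rgs5, a pericyte gene, called lower (-1.13, SE 0.22). Of the hepatocyte markers Alb, serum albumin, rose 1.82-fold, while the list's median was 0.12 (adjusted p = 0.0798). The skeletal muscle list had a median of -5.58 (adjusted p = 0.0274, 0.662 with an estimated correlation), in a comparison that holds the library with muscle transcripts. Without that library it was -1.04 and still called, and its call ended without ko_normal replicate 2 (adjusted p = 0.0645), wt_HFD replicate 1 (0.0779) or ko_HFD replicate 3 (0.0605), and with total count scaling (0.0735).

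Of 14 clock genes, 3 rose and 1 fell in ko livers averaged over both diets. Arntl, which encodes the clock activator BMAL1, fell by 1.90 on the log2 scale (SE 0.35), and Dbp, a clock output factor, rose 6.79-fold, with Per2 (2.68-fold) and Hlf (1.68-fold) also called higher. Dbp was at 5.91 ± 6.6 CPM in wt_normal, 132 ± 51 in ko_normal, 49.7 ± 39 in wt_HFD and 104 ± 26 in ko_HFD (SD, n = 3). The list's median was 0.52 (camera adjusted p = 0.0961), with 7 members higher and 2 lower when adjusted over the list alone. With the log2 ratio of Arntl to Dbp as a covariate, chosen after the data were seen, 37 genes were called instead of 168, 8 of them shared. Of the 41 called genes named for this comparison, 39 lost their call, Sqle among them (1.24, adjusted p = 0.231 in a range of 0.00145 to 0.231). Dbp changed sign in that fit, so of these genes only Trp53 kept its call. Arntl, among those that lost it, and Dbp are themselves part of the ratio. Every ko library lay below every wt library in the ratio, so these losses cannot tell clock phase from genotype.

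**Figure D4:**
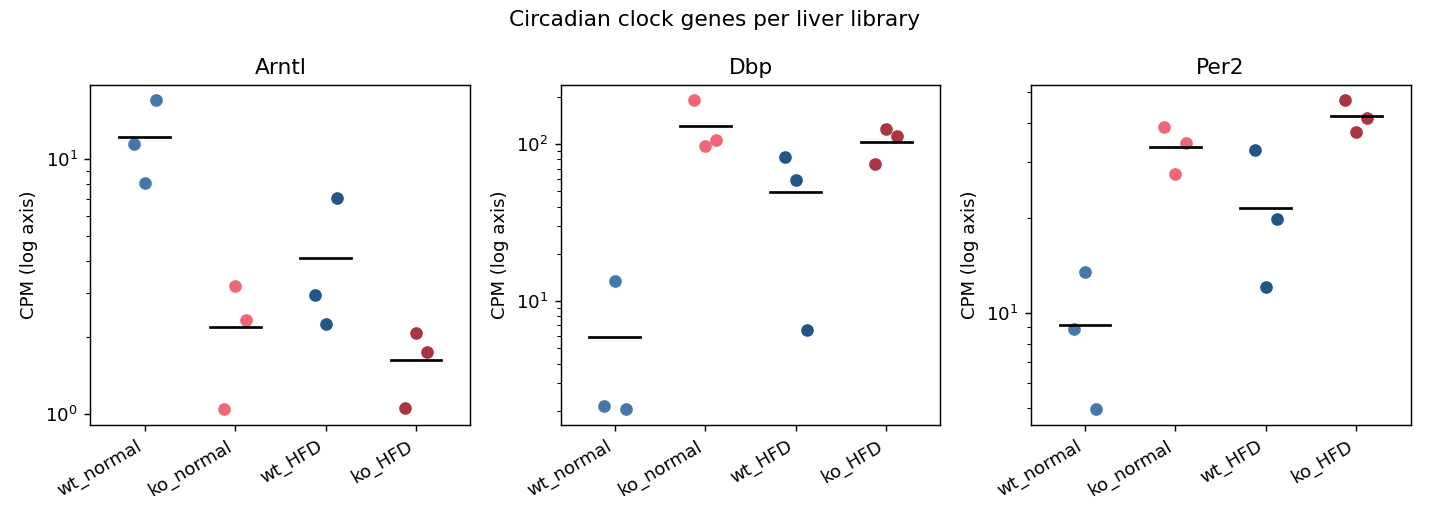
Normalised read count in CPM (log axis) of the clock genes Arntl, Dbp and Per2 in the 12 liver libraries by group. Points are libraries and lines are group means of 3. Mean Dbp was 5.91 CPM in wt_normal and 132 CPM in ko_normal.

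The other named rises averaged over both diets were Rgs16 (7.89-fold), Lrmda (17.5-fold), Clec2h (5.38-fold) and Car3, carbonic anhydrase 3 of adipocytes and hepatocytes (4.27-fold). Of the mitochondrially encoded genes, whose median was 0.77 (camera adjusted p = 8.38e-05, 0.426 with an estimated correlation), mt-Nd3, a subunit of complex I, rose 3.11-fold. The list's median was 0.32 without ko_normal replicate 1, which with ko_HFD replicate 2 had the highest mitochondrial shares, 14.2% and 9.98%. The tRNA genes on either side of it, mt-Tg at 9391 to 9458 and mt-Tr at 9808 to 9875 of the mitochondrial genome, also rose. Mt-Tg had no count in the 6 wt libraries and was at least 98.8-fold higher, and mt-Tr had a log2 change of 5.39 (SE 0.65). The substrain of the ko and wt mice is not given in the sources used here, and gene counts cannot show whether their mitochondrial sequences, and with them the assignment of reads to these neighbours, differ. The named falls were the proenkephalin gene Penk (-3.86), Srp54a (-3.44), the growth factor binding protein gene Igfbp1 (-2.98), Cpe (-2.91), the phosphatase gene Dusp8 (-2.60) and Csgalnact1 (-2.08).

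The count of 168 genes was 45 without ko_normal replicate 3, 55 without wt_normal replicate 3, 63 without wt_normal replicate 2, 64 without ko_HFD replicate 3, 68 without wt_HFD replicate 3, 72 without ko_HFD replicate 2, 80 without ko_normal replicate 1, 99 without wt_HFD replicate 2 and 254 without wt_HFD replicate 1. Trp53 kept its call in all 20 alternatives, and Cdkn1a, Slc2a2, Akr1d1 and Cyp2a5 in all but the fit with the clock covariate. Of the 41 called genes named for this comparison, 6 to 26 lost their call with 1 library left out, most without ko_normal replicate 3 (26) and wt_normal replicate 3 (25). Insig1, Scarb1, Stard4, Hlf, Dhcr7 and Nsdhl each lost theirs in 14 of 20 alternatives. With libraries scaled by total count, 60 genes were higher and 66 lower, against 114 and 54.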

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

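Of the tests in this part, the fit with the clock index and the 9 exchanges of HFD libraries were chosen only after the results were seen. In the difference between the ko effects on HFD and on normal diet, 9 lists were called by camera with the preset correlation, and each is given because the interaction test itself passed for it. None was called with an estimated correlation, where the adjusted p ran from 0.193 to 0.645, nor by fry. ER stress genes had a median log2 difference of -0.813 (adjusted p = 3e-11, 0.193 with an estimated correlation), with 17 of 17 members negative. Creld2, an ER stress-induced gene, was at 39.7, 85.9, 120 and 101 CPM in wt_normal, ko_normal, wt_HFD and ko_HFD. Acute phase genes had a median of -0.836 (adjusted p = 4.52e-05) and sterol sensing and uptake -0.381 (adjusted p = 0.0365). Xenobiotic metabolism had a median of 0.39 (adjusted p = 0.00399) and male-biased genes -0.328 (adjusted p = 0.0105). The acute phase median was -0.53 without wt_normal replicate 1, -0.54 without wt_HFD replicate 2, and -1.74, -0.48 and -0.38 without ko_HFD replicates 1, 2 and 3. The xenobiotic median was 0.60 without ko_normal replicate 1 and 0.68 without wt_HFD replicate 3, and the male-biased median -0.08 without ko_normal replicate 1, -0.58 without ko_normal replicate 2, -0.50 without wt_HFD replicate 3 and -0.58 without ko_HFD replicate 3. With an estimated correlation these 4 lists (acute phase, sterol sensing, xenobiotic and male-biased) had adjusted p = 0.581, 0.285, 0.47 and 0.492.

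Of the lists of cell type markers, 4 were called with positive medians, and no member of them passed alone over all genes. Endothelial markers had a median of 0.609 (adjusted p = 0.0128), stellate cell markers 1.04 (adjusted p = 0.00192), T and NK cell markers 1.85 (adjusted p = 0.000143) and B cell markers 3.29 (adjusted p = 0.00409), with adjusted p = 0.645, 0.492, 0.285 and 0.492 with an estimated correlation. Only 9 of 14 T and NK and 5 of 8 B cell markers were tested, at low levels. Their wt_HFD means ran from 0.0567 (Cd8a) to 1.33 CPM (Cd4) and from 0.307 (Cd79a) to 4.47 CPM (Ighm). Library wt_normal replicate 2, which held muscle and B cell transcripts, enters this difference. Without it the medians were 0.49, 0.74, 1.08 and 1.05, each still called. The endothelial median was 0.18 without ko_HFD replicate 3. With the clock index as covariate the endothelial and male-biased calls ended (adjusted p = 0.357 and 0.0683), and without a filter on low counts that of sterol sensing (0.0587). The stellate median was 1.86 without wt_HFD replicate 2 and 0.67 without wt_HFD replicate 3, and the T and NK median 1.10 without ko_normal replicate 3. The calls of sterol sensing and male-biased genes ended without wt_normal replicate 2 (adjusted p = 0.0607 and 0.0773). Sterol sensing also lost its call without wt_normal replicate 1, ko_normal replicate 2, wt_HFD replicate 3 or ko_HFD replicate 1 (adjusted p = 0.0892, 0.0936, 0.0916 and 0.0706). Male-biased genes lost theirs without ko_normal replicate 1, wt_HFD replicate 2, ko_HFD replicate 1 or ko_HFD replicate 2 (0.0851, 0.174, 0.0558 and 0.0673), endothelial markers without ko_normal replicate 3, wt_HFD replicate 1 or ko_HFD replicate 3 (0.167, 0.141 and 0.208) and xenobiotic metabolism without ko_HFD replicate 1 (0.0924).

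Other splits of the libraries called as many lists. For the difference, 24 of 100 splits gave 9 or more lists, with 16 in the highest of the others, so chance cannot be excluded for that number of lists. No gene was called for it by edgeR in the real groups, which 100 of 100 splits equal or exceed. There were 725 genes at an unadjusted p under 0.05, near what chance alone gives, and 19 adjusted by DESeq2 and 1 by voom with sample weights. The split with most genes, 161, exchanged wt and ko on the normal diet and set wt_HFD replicate 1 and ko_HFD replicates 1 and 2 against wt_HFD replicates 2 and 3 and ko_HFD replicate 3. It adds the ko effect on normal diet to that of HFD groups with wt_HFD replicate 1 and ko_HFD replicate 3 exchanged. The next highest of the 100 was 11. Why this split gave 161 genes was not tested.

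For ko against wt averaged over both diets, 1 of 100 splits, the real one, gave 168 genes, and the highest of the others gave 11. A share under 0.05 of the splits drawn thus reached 168, which argues against chance for that count but does not exclude it. The highest value of 11 depends on which 100 of the 200 splits were drawn. The real normal-diet groups with wt_HFD replicate 1 and ko_HFD replicate 3 exchanged were not among them and gave 161 genes for the average. The other 8 of the 9 exchanges of 1 wt_HFD with 1 ko_HFD library keep as many genotypes and gave 0 to 11 genes. The number of genotypes kept thus does not by itself account for the 161. Each exchange keeps different libraries, and whether those kept here matter was not tested. For its 12 lists, 11 of 100 splits gave as many, with 16 in the highest other, so chance cannot be excluded. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For ko against wt on normal diet 1 of 10 gave 30 genes (highest other 0) and 2 of 10 gave 13 lists (highest other 14). On HFD 1 of 10 gave 10 genes (highest other 5) and 2 of 10 gave 11 lists (highest other 11). For HFD in wt 1 of 10 gave 100 genes (highest other 1) and 4 of 10 gave 11 lists (highest other 13). For HFD in ko 10 of 10 gave 0 genes or more (highest other 0) and 9 of 10 gave 3 lists (highest other 9).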

How the results depend on the processing

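The fit with the clock index as covariate and the exact permutation of list means were chosen only after the results were seen, and the other alternatives before. Numbers below are genes called for ko against wt on normal diet, on HFD, HFD in wt, HFD in ko, the difference of the ko effects and the average, where the main values were 30, 10, 100, 0, 0 and 168. Without a filter on low counts they were 648, 51, 696, 21, 13 and 644, with 26294 genes tested and the prior degrees of freedom at 20.9 instead of 4.66. DESeq2's Wald test gave 529, 95, 665, 37, 19 and 860. In simulated data it made 23 false calls in ko against wt on normal diet where edgeR made 2. False calls for the average were 27 by DESeq2 and 11 by edgeR, and for HFD in wt 24 and 6. Voom with sample weights gave 2707, 5, 363, 6, 1 and 898, with weights of 5.40 for ko_normal replicate 3 and 3.29 for wt_normal replicate 3 against 0.356 to 1.15 for the others. With only the 2 groups compared the first 4 were 96, 6, 34 and 2. Total count scaling gave 18 and 16 for the first 2. It put the median log2 change of all genes at -0.16 on normal diet, -0.21 for HFD in wt and 0.17 for the difference. These medians were -0.02, -0.03 and 0.007 in the main fit. On HFD it gave 12 higher and 4 lower, and DESeq2 size factors 11 and 4, against 6 and 4. A 2-fold minimum left 91 genes in the average. The clock covariate gave 73, 3, 157, 0, 8 and 37, sharing 5, 3, 31, 0, 0 and 8 genes with the main fit's calls. The cause was not tested for any of these changes in count. Leaving out 1 library gave 3 to 84, 2 to 14, 9 to 131, 0 to 6, 0 to 1 and 45 to 254.

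Whether replicate numbers pair the libraries could not be settled. Of 18 pairs with the same number 4 had a correlation above 0.1, and 7 of 12 libraries correlated best with their own number. With the replicate block the counts were 45, 7, 91, 0, 0 and 157, and the list calls of clock and male-biased genes on normal diet and of immediate early genes for HFD in wt ended. Sqle averaged over both diets was at 0.94 with the block (adjusted p = 0.0649), 0.872 with total count scaling (adjusted p = 0.0648) and 1.236 with the clock covariate (adjusted p = 0.231), in a range of adjusted p from 0.00145 to 0.231, and 0.827 to 1.082 with 1 library left out. On the normal diet it passed with voom and sample weights (1.06, adjusted p = 0.0115, range 0.0115 to 0.456), and on HFD in none of 21 alternatives.

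Lists called by camera numbered 13, 11, 11, 3, 9 and 12. With an estimated correlation they numbered 0 in each comparison, and those that fry also called numbered 5, 4, 3, 1, 0 and 9. The exact permutation of list means called 7 in the average, 5 of them shared, and gave cholesterol synthesis adjusted p = 0.0619. It also called cholesterol efflux (adjusted p = 0.0413) and clock genes (0.0471), which camera did not call. It lost interferon response, mitochondrially encoded and stellate genes (0.0825 each), skeletal muscle (0.106), xenobiotic metabolism (0.11) and acute phase genes (0.284). With 1 library left out, the lists numbered 7 to 13 on HFD, 5 to 12 for HFD in wt and 2 to 9 for HFD in ko.

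The following values changed sign. Trp53 for HFD in wt was 0.188 and 0.126 without wt_HFD replicate 1 and 2 (range -0.686 to 0.188 over left-out libraries), and 0.359 with the clock covariate. Trp53 for HFD in ko was 1.101 without ko_normal replicate 1 (range -0.437 to 1.101) and 1.157 with voom. In the difference of the ko effects, Trp53 was -0.282, -0.366, -0.221 and -0.167 without ko_normal replicate 2, ko_normal replicate 3, wt_HFD replicate 1 and wt_HFD replicate 2 (range -0.366 to 1.186), and -0.432 with the clock covariate, and Sqle was -0.07 without ko_HFD replicate 1 (range -0.07 to 0.5), -0.143 with voom and -0.003 with the clock covariate. With that covariate Trp53inp1 in the average was 0.263 and the mitochondrially encoded list on normal diet -0.183. Dbp in the average was -0.169, which says little, since Dbp is part of the index that the fit holds constant. The immediate early list on HFD was at -0.063 without wt_HFD replicate 3 (range -1.571 to -0.063), where camera's direction was up and the median stayed below 0. Over the named genes, 2250 values kept direction and side of the threshold, 651 lost the call, 76 gained it and 15 changed sign. In simulated data with these libraries, 19.4% of 2-fold changes were recovered for ko against wt on normal diet and 46.4% for the average, and what depth and the number of libraries each limit was not separated.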

Other observations

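The tests of the cholesterol synthesis genes, the muscle transcripts and the clustering of called genes were chosen only after the results were seen, and the test of the Trp53 neighbourhood before. The lists that camera did not call in ko against wt averaged over both diets included the following. Cell cycle genes had a median log2 change of 0.10 (adjusted p = 0.824), fatty acid oxidation and PPARalpha targets -0.12 (0.211), lipid droplet genes -0.22 (0.42), oxidative stress genes -0.11 (0.82), glucose metabolism 0.02 (0.74) and macrophage markers -0.07 (0.561). Cholesterol efflux and esterification had 0.09 (0.145). Male-biased genes had 0.15 (0.4), female-biased genes -0.15 (0.794), Y-linked genes 0.31 (0.105), immature thymocyte markers -0.11 (0.4), cholangiocyte markers -1.04 (0.502), neutrophil markers -0.34 (0.211), adipocyte markers 0.97 (0.502) and erythroid markers 0.19 (0.865). T and NK cell markers had 0.36 (0.0798), B cell markers -0.37 (0.824), ER stress genes 0.10 (0.82) and immediate early genes -0.78 (0.265). The pancreatic list had 2 tested members and was not tested. Of 14433 genes, 130 lay higher in every ko library than in every wt library and 122 lower. If all 12 libraries were exchangeable whatever their diet, 15.6 each would be expected. Genes are not independent, so no p is given for that excess.

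Of 20 cholesterol synthesis genes 5 rose in ko livers, and the mean difference over all 20 was 0.335 (SE 0.0976), with adjusted p = 0.195 with an estimated correlation and 0.0619 by exact permutation. A different clock phase of the ko libraries was weighed, since the log2 ratio of Arntl to Dbp ran from -0.732 to 2.99 in wt_normal and from -7.37 to -4.88 in ko_normal, and was -4.77, -4.64 and 0.118 in wt_HFD and -6.00 to -5.84 in ko_HFD. With that ratio in the model the difference was 0.613 (SE 0.167), above the limit of 0.167 set for this explanation. However, every ko library lies below every wt library in that ratio. Trp53 itself lost its call on normal diet in that fit (-3.44, adjusted p = 0.137 by edgeR). The ratio thus follows the genotype, so this fit cannot tell clock phase from genotype. A higher share of hepatocyte RNA would raise hepatocyte markers alike, and their median was 0.121 against 0.419. The SE of the difference, 0.133, comes from a bootstrap over genes and does not measure the spread between libraries. Alb (0.86) and the endothelial (-0.71) and stellate (-0.96) medians go with such a share, and the macrophage median (-0.07) does not. Without wt_normal replicate 2 the median was 0.455, which argues against that library as the whole cause. Over these genes the hepatocyte markers argue against a hepatocyte share as the whole cause, and a part from it stays open. A different clock phase stays open too. An effect of the p53 genotype stays open as a hypothesis. Other causes may add to it, such as feeding state or sampling time, which the labels do not give.

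Muscle transcripts in wt_normal replicate 2 may come from skeletal muscle tissue in that library. All 8 markers lay at 20 times the highest other library or more, Acta1 at 3235 CPM, Tnnt3 at 2292 CPM and Myh1 at 1484 CPM. A ko library under a wt label is argued against, since Trp53 was at 14.5 CPM there against at most 1.62 CPM in a ko library. No biological explanation was tested.

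Ko mice can carry a segment of the donor strain around the deleted gene, so clusters of called genes were looked for, first in windows of 10 Mb although 20 Mb had been written down. The densest window of 10 Mb held 6 called genes (permutation p = 0.52 over 10000 draws), Trp53 itself, where it starts on chromosome 11, and 5 of the genes of the next test. The densest window of 20 Mb, on chromosome 12, held 8 of 76 tested (permutation p = 0.4), so chance is not excluded. Trp53 left out, within 10 Mb of it 6 of 294 tested genes were called, Pipox, Srebf1, Tlcd2, Tnfaip1, Inca1 and Xaf1, against 3.37 by chance (exact hypergeometric p = 0.12). Whether a carried segment adds to these calls cannot be told apart from the effect of the deletion, since the ko genotype and the segment are the same libraries.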
